A study of Mus musculus and Homo sapiens with 23 samples.

How the data were processed

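RNA was measured in BV2 cells, an immortalised line of mouse microglia, the resident macrophages of the brain. One library came from unstimulated cells and 1 from cells stimulated for 3 h with lipopolysaccharide (LPS), the outer membrane component of Gram-negative bacteria. Per the labels' protocols, total RNA was extracted with Trizol, libraries were made with a strand-specific kit (NEBNext Ultra Directional) and reads were 76 bases long. Whether ribosomal RNA was removed or polyadenylated RNA selected is not given in the sources used here. The series lists 23 samples. The other 21 are chromatin immunoprecipitation or input samples of BV2 cells, mouse embryonic forebrain, mouse embryonic stem cells and the human lymphoblastoid line GM12878, and they were not analysed here.

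The authors deposited, for each of the 2 libraries, a table of FPKM values (fragments scaled to transcript length and library size) with a lower and an upper bound of the FPKM and an estimation status. Per the submitters' processing notes, the tables come from Cufflinks and the genome build is mm9, and the version of Cufflinks and the aligner are not given in the sources used here. Each table held 28246 rows, 1 per RefSeq transcript and locus, and the same set in both. The bounds are a 95% interval of Cufflinks that covers counting and the assignment of fragments inside a library, not the spread between cultures. No gene symbols stood in the tables. Symbols were taken from a RefSeq gene table of assembly GRCm38.p6, used for names only, which matched 27560 rows (97.6%) and 98.5% of the 11673 rows with an FPKM of 1 or more in either library. Coordinates are the deposited mm9 loci, written 1-based. The deposited starts were read as 0-based, because end minus start equalled the gene length of the name table for 6620 of 8257 genes with 1 transcript, and for 289 when 1 was added.

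Rows whose status was not OK in both libraries (391 rows) and rows of small RNA genes (704 further rows, symbols of microRNA, snoRNA, scaRNA and small nuclear RNA genes) were left out, and rows of the same symbol were summed, with half-widths of the intervals combined in quadrature. This gave 21597 genes, of which 10035 had an FPKM of 1 or more in either library and were counted. For 11 counted genes, part of the rows were among those left out. The change of a gene is log2(FPKM + 1) of the LPS library minus that of the unstimulated library. The pseudocount of 1 understates the change of genes with low FPKM. With 1 library per group no test across replicates was possible, no p-value is given, and every difference compares these 2 libraries rather than the conditions. A gene was called higher or lower by a fixed rule of size, a change of at least 1, which is a fold of 2 on this scale. It was recorded separately whether the 2 deposited intervals overlapped. Ratios of FPKM without the pseudocount are given with a 95% interval obtained from both deposited intervals, and no ratio is given for a gene listed at 0 or supported by 3 or fewer implied fragments in a library.

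Depth was read from the deposited intervals. Where the half-width is 2 standard deviations of a count, 2 × FPKM divided by the half-width, squared, gives the number of fragments behind a value. Among rows with 0.5 to 50 such fragments, 67.5% of 5069 rows in the unstimulated library and 68.9% of 5159 rows in the LPS library came within 0.05 of a whole number, against 10% by chance. Over 2626 rows with whole numbers in both libraries, the FPKM denominator of the LPS library was 1.05 times that of the unstimulated library. The implied fragments of rows with status OK summed to 13800000 in the unstimulated and 16930000 in the LPS library, to the nearest 10000.

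Gene lists were fixed before the data were examined. They comprised interleukins, TNF family and growth factors; chemokines; NF-kB subunits and inhibitors; the TLR4 receptor complex and its adaptors; other Toll-like and pattern receptors; interferon-stimulated genes; immediate early and AP-1 genes; feedback phosphatases, SOCS and RNA decay factors; inflammatory effector enzymes; NRF2 targets; microglia homeostatic genes; activation surface receptors; antigen processing and MHC; inflammasome and cell death; cholesterol synthesis; LXR and lipid handling; glycolysis; cell cycle; the TGF-beta pathway; histone acetylation writers, erasers and readers; the unfolded protein and heat shock response; housekeeping references; ribosomal proteins; the mitochondrial chromosome; and markers of neurons, astrocytes, oligodendrocytes, fibroblasts with endothelium, and lymphocytes. The tables held 0 rows on the mitochondrial chromosome, so that list has no value. Each list is described by its counted members, the number past the size rule and the median change. The median's percentile among 10000 random lists of the same size, matched on mean log2(FPKM + 1) in 20 bins, is a description of these 2 libraries. In the closing section 10 further lists were added after the tables had been opened, the G1/S, G2/M, p53, iron and receptor lists after values of members or of the cell cycle list had been seen.

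Genes named in the text follow a rule fixed before the data were examined. It takes the 10 largest rises and 10 largest falls among counted genes with an FPKM of 5 or more in the higher library and intervals that do not overlap. From each list it takes the 2 members with the largest rise and the 2 with the largest fall past the size rule, or, where none passed, the 2 with the largest change. It always takes 21 genes central to LPS signalling, TGF-beta signalling, microglial identity or normalisation, and it takes the 5 most abundant genes of each library. Genes outside the rule are named only to complete a count of 5 or fewer, or where the sentence says so, and were chosen after their values were seen. A few genes that the rule takes are not reported here.

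The alternatives were pseudocounts of 0.1 and 5, no filter and a filter at an FPKM of 5, scaling to a median log2 ratio of 0, rescaling each library to the same sum (TPM), quantile normalisation, inclusion of all rows, each row on its own, and folds of 1.5 and 4. Calling was tested on simulated libraries of 9726 genes made from the unstimulated library's fragments in the comparison of LPS with unstimulated cells. It recovered 42 of 50 genes changed 2.5-fold, 48 of 50 changed 4-fold, 50 of 50 changed 8-fold and 0 of 50 changed 1.5-fold. It called 7 of 9526 unchanged genes, 0 of them with separate intervals. The simulated libraries differ by counting error only, with no spread between cultures, so these counts give no error rate for the real comparison. Intervals were separate for 52 of the 9526 unchanged simulated genes, against 5303 of the 7929 real genes called neither higher nor lower. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.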

Results

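The RNA data comprised 1 library of unstimulated BV2 cells and 1 library of BV2 cells stimulated with LPS for 3 h. The series was designed to follow a histone acetylation mark, H2BK20ac, across cell types and through the change of state of microglia on LPS, and the RNA libraries give the expression side of that transition. Of 28246 transcript rows, 17920 were above 0 in the unstimulated and 17592 in the LPS library. The implied fragments of rows with status OK summed to 13800000 and 16930000, to the nearest 10000. These sums do not measure relative depth, as the FPKM denominator of the LPS library was 1.05 times that of the unstimulated library. There were no replicates, so no difference has a replicate check. An interval after an FPKM value is the deposited 95% interval of that single library, combined over rows for genes of more than 1 row. Intervals of ratios draw on both libraries, and ranges of random lists and of shuffled calls were computed here.

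After 3 h of LPS, cytokine, chemokine and interferon-stimulated genes were strongly higher in the BV2 library and cell cycle genes were lower. Cxcl10, a chemokine that attracts T cells (mm9 chromosome 5, 92775667 to 92777880), went from an FPKM of 1.43 (0.880 to 1.98) to 2666 (2643 to 2690), the largest rise on the log2(FPKM + 1) scale (10.10). Acod1, which makes itaconate, rose from 0.936 (0.668 to 1.203) to 1165 (1155 to 1174), and Il1b, the inflammasome substrate interleukin 1 beta, rose from 1.18 (0.739 to 1.61) to 841.5 (830 to 853). The largest fall was that of Gpr183, an oxysterol receptor that guides immune cell migration, from 30.6 (29.2 to 32.0) to 0.237 (0.115 to 0.360). Of 10035 counted genes, 858 were higher and 1248 lower by the size rule, and the deposited intervals were separate for 851 and 1233 of them. Rises were larger than falls on the log2(FPKM + 1) scale. On that scale 359 genes rose at least 4-fold and 127 fell at least 4-fold, and 107 against 2 passed 16-fold. The pseudocount shrinks rises and falls where 1 value is low: without it Gbp2 rose 1266-fold and Eepd1 fell 29.3-fold. The higher genes held 4.41% of the summed FPKM in the unstimulated and 19.0% in the LPS library, and the lower genes 5.03% and 1.46%.

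The direction of the overall split depends on scaling. Higher genes made up 40.7% and lower genes 59.3% of those called on the deposited FPKM. After rescaling to TPM, which moved the median change of the same genes by -0.24, they made up 24.6% and 75.4%, and after quantile normalisation, which moved it by 0.16, they made up 53.3% and 46.7%. With a pseudocount of 5, 577 genes were higher and 354 lower, so the split depends also on genes of low FPKM.

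**Figure D1:**
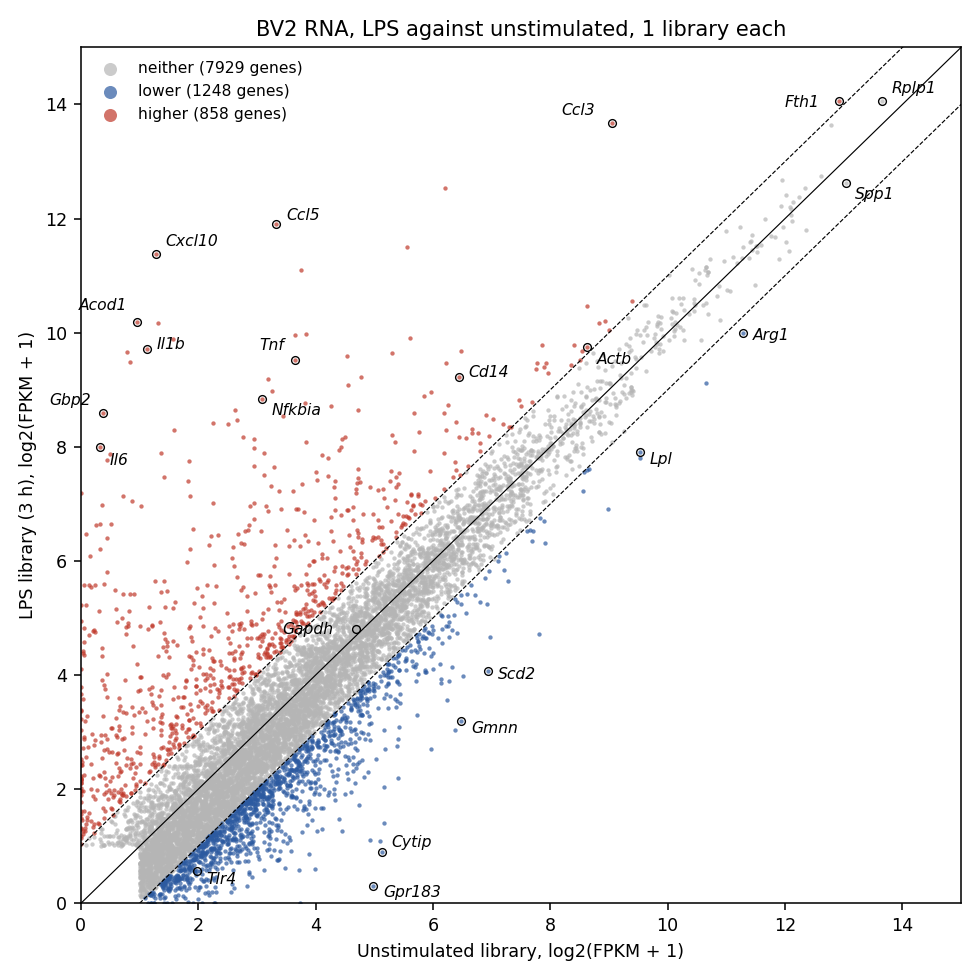
Expression of the 10035 counted genes as log2(FPKM + 1) in the unstimulated library (x axis) and the LPS library (y axis), 1 point per gene, with the line of equality (solid) and the limits of the size rule (dashed). The 858 higher genes (red) reach farther from the line than the 1248 lower genes (blue), with Cxcl10 at a change of 10.10 and Gpr183 at -4.67.

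The other 7 of the 10 largest rises included the interferon-stimulated genes Ifit1, which binds foreign RNA (0.729 to 808 FPKM; mm9 chromosome 19, 34715379 to 34724499), the antiviral radical enzyme Rsad2 (1151 after LPS), the ubiquitin-like Isg15 (1.98 to 952) and the guanylate-binding protein Gbp2 (0.303 to 384). Cmpk2, a mitochondrial nucleotide kinase that lies beside Rsad2 on chromosome 12, rose from 0.793 to 715. The chemokine Ccl5 rose from 9.05 to 3827 and Il6 from 0.258 (0.0272 to 0.488) to 254 (247 to 261). After Gpr183, the largest falls were those of Cytip, a regulator of cytohesin (34.0 to 0.854 FPKM), the GTPase-activating protein Arhgap19 (33.0 to 1.14), the Ras activator Rasgrp3, Rmrp, Rpl26, Eepd1 (14.9 to 0.509), Tmem273 (81.7 to 7.24), the replication licensing inhibitor Gmnn (88.3 to 8.13) and the small GTPase Rab7b (61.5 to 5.51). Rasgrp3 is less certain than the others, with an interval of 2.57 to 67.6 in the unstimulated library. The value of Rmrp, a short structured RNA (34.9 to 1.66 FPKM), rests on 3 implied fragments in the LPS library. The ribosomal protein gene Rpl26 (12.3 to 0.00244 FPKM), of a family with many pseudogenes, is also uncertain, because fragments of near-identical copies can be assigned either way.

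Cytokine genes rose as a group. All 19 counted members of the list of interleukins, TNF family and growth factors rose, with a median change of 2.19 that lay above all 10000 matched random lists. The filter has a part in this, because a member below 1 FPKM when unstimulated was counted only where the LPS library reached 1. Another 4 measured members were below 1 FPKM in both libraries and were left out. Tnf, the founding member of its family, went from 11.49 (10.3 to 12.7) to 735 (725 to 744), a ratio of 63.9 (57.6 to 71.0). The ratio was 986 (410 to 2370) for Il6, the acute phase cytokine, and 716 (497 to 1030) for Il1b. Of 14 counted chemokine genes, 12 rose and 1 fell, with a median of 4.70, above all 10000 random lists. A further 6 measured chemokine genes were below 1 FPKM in both libraries and were left out. Ccl2, which recruits monocytes, rose from 45.8 (42.1 to 49.5) to 2897 (2868 to 2926), and Ccl3 rose from 527 to 13123 FPKM, which placed it among the 5 most abundant genes of the LPS library. Ccl6 was the member that fell, from 15.8 to 5.70 FPKM (a change of -0.96 with a pseudocount of 5, short of the size rule).

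NF-kB pathway genes and the negative regulators of LPS signalling rose. Of 24 counted NF-kB subunits, inhibitors and regulators, 17 rose and 0 fell (median 3.03, above all 10000 random lists). Nfkbia, the inhibitor that NF-kB itself induces, rose 60.7-fold (53.2 to 69.2), from 7.48 to 454 FPKM, and the signalling adaptor Traf1 rose from 0.0644 to 87.5. Among 18 feedback phosphatases, SOCS proteins and RNA decay factors, 10 rose and 1 fell (median 1.35, above all 10000 random lists). The cytokine signalling inhibitors Socs3 and Cish rose 18.7-fold and 12.9-fold, and the RNA decay factor Zfp36l1 fell from 9.69 to 1.75 FPKM.

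Genes of the LPS receptor complex, its adaptors and the signalling proteins downstream of them went both ways. Of the 20 counted members of this list, 4 rose and 2 fell. The list median was -0.04 on the deposited FPKM (92.3rd percentile of random lists), and its sign changed to 0.02 after median scaling and to 0.18 after quantile normalisation. It was also above 0 with a filter at 5 FPKM and with each transcript on its own. Cd14, the LPS co-receptor, rose from 85.9 (82.4 to 89.4) to 593 (584 to 602), and the adaptor Myd88 rose from 12.3 to 75.5. The other 2 that rose were Irak3 (1.35 to 8.34) and Irak2 (9.37 to 34.3, with overlapping intervals). Tlr4, the receptor, fell from 2.92 (2.54 to 3.31) to 0.488 (0.336 to 0.640), and its adaptor Ticam2 fell from 3.69 to 0.949. At these levels the pseudocount matters, and neither Tlr4 nor Ticam2 passed the size rule with a pseudocount of 5, nor did Ticam2 after quantile normalisation. Among 13 other Toll-like and pattern receptors, 6 rose and 2 fell (median 0.90, above 9998 of 10000 random lists). The scavenger receptor Marco (0.153 to 26.4 FPKM) and the mycobacterial lipid receptor Clec4e (48.0 to 957) had the largest rises, and the nucleic acid sensors Tlr13 (23.8 to 4.95) and Tlr8 (3.51 to 0.147) fell, Tlr8 not past the size rule with a pseudocount of 5.

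Immediate early and AP-1 genes rose in part at 3 h. Of 21 counted, 9 rose and 1 fell (median 0.66, above all 10000 random lists). The AP-1 subunit Junb rose from 38.4 to 296 FPKM and the early response gene Ier3 from 40.4 to 177, whereas Fos, the prototype immediate early gene, fell from 12.96 (11.8 to 14.1) to 2.27 (1.81 to 2.73).

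All 39 counted interferon-stimulated genes rose, by 1.40 to 8.87 on the log2 scale. Their median of 5.33 was the highest of the lists fixed before the data were examined and lay above all 10000 random lists. As with the cytokines, members below 1 FPKM when unstimulated were counted only where the LPS library reached 1. There was 1 further measured member, below 1 FPKM in both libraries and left out. Ifit1 rose 1108-fold (809 to 1517) and Rsad2 768-fold (641 to 920). Irf1, a transcription factor of the interferon response, rose from 6.72 (4.09 to 10.4) to 252 (247 to 257). Antigen presentation genes of MHC class I rose with them. In the list of antigen processing and MHC, 13 of 18 counted genes passed the size rule, 0 fell, and the median of 1.53 lay above all 10000 random lists. The 5 within the rule were B2m, Erap1 (a change of 0.90) and the class II-related Cd74 (0.92), H2-DMa (0.71) and H2-DMb1 (0.18). Below 1 FPKM in both libraries were 4 class II genes: H2-Aa (0.0526 and 0), H2-Ab1 and H2-Eb1 (0 in both) and the regulator Ciita (0.0092 and 0.0788). The peptide transporter Tap1 rose from 3.64 (0.826 to 7.50) to 85.2 (82.2 to 88.1), and its partner tapasin, Tapbp, rose from 4.03 to 86.9. B2m, the light chain of MHC class I and one of the 5 most abundant genes in both libraries, was at 7050 and 12792 FPKM, a change of 0.86 that did not pass the rule.

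**Figure D2:**
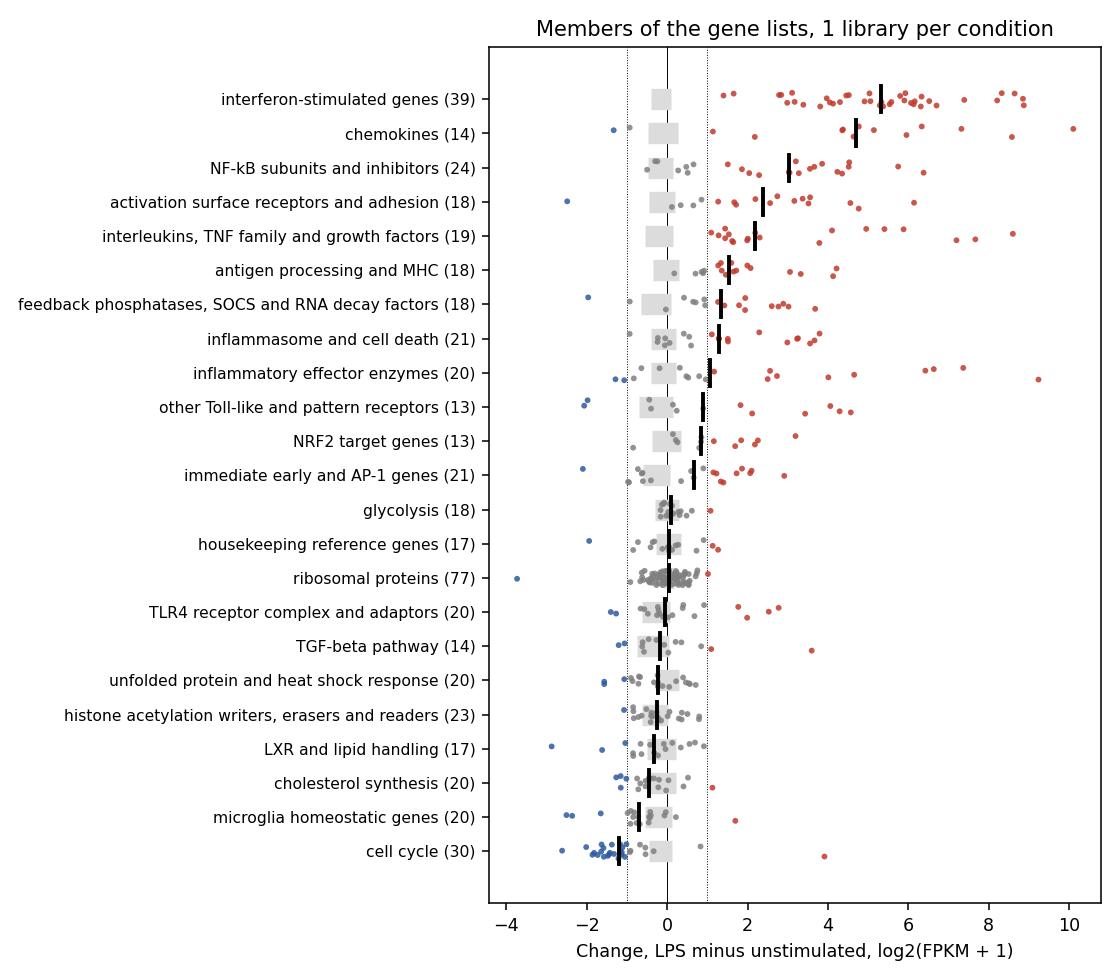
Change between the LPS and the unstimulated library on the log2(FPKM + 1) scale (x axis) for each counted member (points) of the 23 fixed lists with at least 10 counted genes (y axis, number of genes in parentheses), with the list median (black bar) and the central 95% of medians of 10000 matched random lists (grey). Red and blue points passed the size rule; medians ran from -1.19 for the cell cycle to 5.33 for interferon-stimulated genes.

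Effector enzymes and activation receptors rose. Among 20 inflammatory effector enzyme genes, 10 rose and 2 fell (median 1.07, above all 10000 random lists). Nos2, the inducible nitric oxide synthase, rose from 0.649 (0.473 to 0.826) to 140 (138 to 143), Ptgs2, the inducible cyclooxygenase, from 2.76 (2.40 to 3.12) to 93.5 (91.5 to 95.6), and the acute phase protein gene Saa3 from 12.4 to 2204. The 2 that fell were Ptgs1, the constitutive cyclooxygenase (16.8 to 7.49), and Arg1, the arginase that uses the same substrate as nitric oxide synthase (2491 to 1023). Ptgs1 no longer passed the size rule after median scaling or quantile normalisation or with a pseudocount of 5. Of 18 activation surface receptors and adhesion molecules, 13 rose and 1 fell (median 2.38, above all 10000 random lists). The co-stimulatory receptor Cd40 rose from 13.3 to 1008 FPKM and the adhesion molecule Icam1 from 7.72 to 236, while the inhibitory receptor Cd200r1 fell from 14.4 to 1.75.

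Genes of cell death control and of the oxidative stress response were also higher. In the list of inflammasome and cell death genes 12 of 21 rose and 0 fell (median 1.28, above all 10000 random lists), with the caspase 8 inhibitor Cflar (5.43 to 88.0 FPKM) and the antiapoptotic Bcl2a1d (21.8 to 288) first. Bcl2a1d belongs to a family of near-identical copies, so its value is uncertain. Of 13 NRF2 targets, 6 rose and 0 fell (median 0.85, above 9997 of 10000 random lists), led by the autophagy receptor Sqstm1 (88.3 to 816) and the thioredoxin reductase Txnrd1 (18.2 to 90.9).

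Genes typical of resting microglia were at low levels in BV2 cells and lower after LPS. Of 20 counted homeostatic genes, 3 fell and 1 rose, and the median of -0.70 lay above 11 of the 10000 random lists. The transcription factor gene Mef2c fell from 8.79 to 0.908 FPKM, as did the complement gene C1qa (4.46 to 0.740, and not past the rule with a pseudocount of 5), and Spi1, which encodes the myeloid factor PU.1, rose from 217 (211 to 223) to 707 (696 to 717). The purinergic receptor gene P2ry12 was at 1.19 (0.875 to 1.51) and 0.223 (0.0887 to 0.358), Tmem119 at 2.16 (1.70 to 2.62) and 0.601 (0.365 to 0.837), and Csf1r at 58.7 (56.9 to 60.4) and 36.3 (34.9 to 37.6). None of these 3 passed the rule, although their intervals were separate. Cx3cr1, the fractalkine receptor, was below an FPKM of 1 in both libraries (0.142 and 0.0615). The number of homeostatic genes called lower was 8 with a pseudocount of 0.1 and 9 after rescaling to TPM. Markers of other cell types were low in both libraries: 0 of 11 neuronal markers were counted, with highest values of 0.140 and 0.171 FPKM. In each of the other lists 1 marker was counted: Aldoc of astrocytes (42.2 and 41.9), Cnp of oligodendrocytes (4.38 and 8.10), Kdr of endothelium (5.45 and 4.79) and Il7r of lymphocytes (1.77 and 0.591), and 0 of these 4 passed the size rule.

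**Figure D3:**
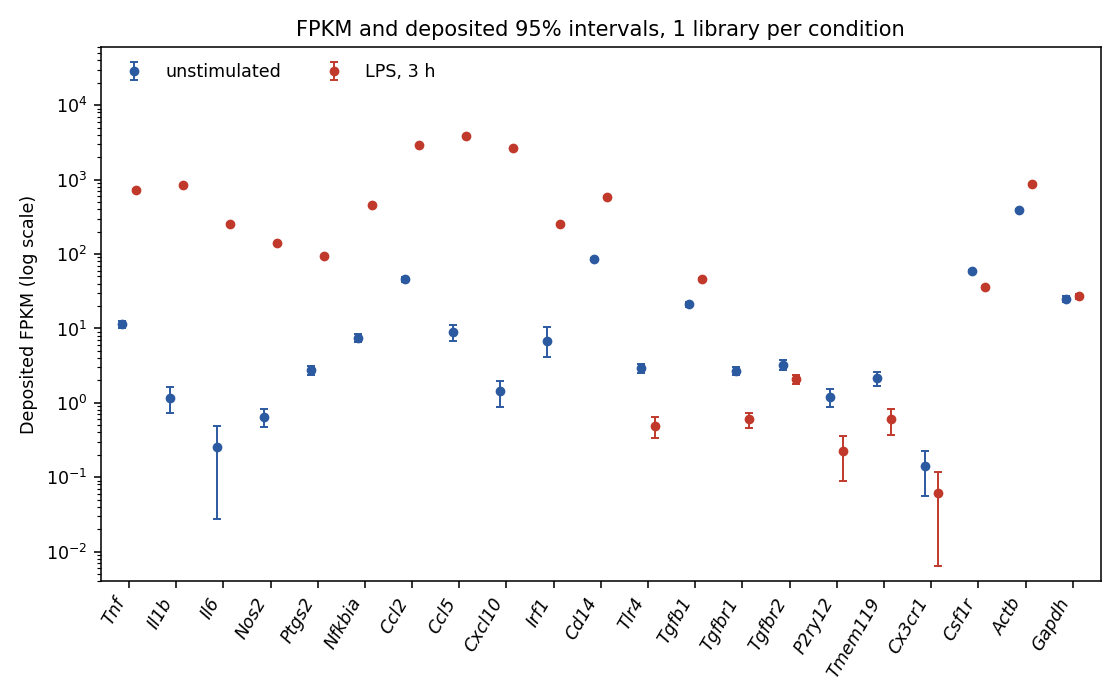
Deposited FPKM (y axis, log scale) in the unstimulated (blue) and LPS (red) libraries for the 21 genes named whatever their values (x axis), with the deposited 95% interval of each library as error bars. Cytokine and chemokine genes were higher after LPS, Tlr4 and Tgfbr1 lower, and Gapdh was at 24.8 and 27.2.

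Lipid genes fell in part. Of 20 counted cholesterol synthesis and uptake genes, 4 fell and 1 rose (median -0.45, percentile 2.80). Dhcr7, the last enzyme of one branch of the pathway, fell from 8.70 to 3.04 FPKM, the sterol carrier gene Stard4 from 5.07 to 1.73, Idi1 from 29.0 to 12.5 and Hmgcs1 from 28.8 to 13.8. With a pseudocount of 5, 0 of these genes were called lower, and Stard4 was not past the rule after quantile normalisation nor Hmgcs1 after median scaling. Among 17 LXR and lipid handling genes 3 fell and 0 rose (median -0.32, percentile 16.9). The desaturase gene Scd2 fell from 122 (119 to 124) to 15.8 (15.0 to 16.5), the lipoprotein lipase gene Lpl from 735 to 239, and Scd1 from 1.61 to 0.271, the last not past the rule with a pseudocount of 5 or after quantile normalisation.

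The glycolysis list stayed close to the random lists. Of 18 counted glycolysis genes, 1 rose, the hexokinase gene Hk1 (9.08 to 20.3 FPKM), and 0 fell. Hk1 did not pass the rule with a pseudocount of 5 (0.85), after TPM (0.88) or with each transcript on its own (0.50). The median of 0.09 was at the 75.3rd percentile and became -0.14 after rescaling to TPM and -0.02 after quantile normalisation. Of 20 genes of the unfolded protein and heat shock response 3 fell and 0 rose (median -0.23, percentile 4.83): the stress transcription factor gene Ddit3 (14.8 to 4.35), the chaperone gene Dnajb9 (25.8 to 8.06) and the disulfide isomerase gene Pdia4 (46.3 to 21.6), which was short of the rule with a pseudocount of 5 and after median scaling.

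Cell cycle genes fell. Of 30 counted, 22 fell and 1 rose, and the median of -1.19 lay below all 10000 random lists. It was between -1.47 and -1.12 under median scaling, TPM and quantile normalisation. Ccne2, the cyclin of the G1 to S transition, fell from 27.3 (25.6 to 29.1) to 3.64 (3.17 to 4.12), and the spindle checkpoint kinase gene Bub1 from 9.24 (8.59 to 9.89) to 1.54 (1.29 to 1.797). The member that rose was Cdkn1a, the cyclin-dependent kinase inhibitor p21, from 25.5 (23.8 to 27.1) to 397 (391 to 404). Cdkn1b, an inhibitor of the same kind named here outside the rule, was among the 22 that fell. With a pseudocount of 5, 13 members were called lower.

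For the TGF-beta pathway, which other BV2 samples of the series address, 2 of 14 counted genes rose and 2 fell (median -0.17, percentile 85.2; above 0 with a filter at 5 FPKM). Tgfb1, the ligand, rose from 21.1 (19.6 to 22.5) to 46.2 (44.2 to 48.3). The receptor gene Tgfbr1 fell from 2.69 (2.39 to 2.99) to 0.603 (0.465 to 0.741) and the repressor gene Ski from 5.00 to 1.89. Tgfbr2 was at 3.22 (2.73 to 3.72) and 2.08 (1.79 to 2.36), a change of -0.46. Of these calls, Tgfb1 was lost after rescaling to TPM (0.87), Tgfbr1 and Ski after quantile normalisation (-0.89 and -0.74), and all 3 with a pseudocount of 5. Among 23 counted histone acetylation writers, erasers and readers, the enzymes and readers of the kind of mark the series studied, 1 fell and 0 rose (median -0.26, percentile 58.5). That gene was Hdac9, a histone deacetylase (3.66 to 1.22), and it did not pass the rule after quantile normalisation (-0.73) or with a pseudocount of 5.

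Reference genes did not all stay level. Of 17 counted housekeeping references 2 rose, among them Actb (392.3 to 862 FPKM), and 1 fell, the transferrin receptor gene Tfrc (42.4 to 10.3). Actb was at changes of 0.89 and 0.81 after TPM and quantile scaling, short of the size rule. Gapdh was at 24.8 (22.7 to 26.9) and 27.2 (25.01 to 29.3), with overlapping intervals and a change that turned to -0.11 after rescaling to TPM. It has many pseudogene copies, so its level is uncertain. The list median was 0.05 (percentile 54.4) and became -0.20 after TPM and -0.23 after quantile normalisation. Of 77 counted ribosomal protein genes, 1 rose, Rpl36 (363 to 736), and 1 fell, Rpl26. Rpl36 was at 0.77 and 0.72 after TPM and quantile scaling, short of the rule. Their median of 0.04 (percentile 46.0) became -0.20 and -0.13 under the same 2 scalings. The most abundant transcripts were those of Rplp1 (12899 and 17183 FPKM), the ferritin gene Fth1 (7725 and 17148), B2m, the galectin gene Lgals1 (6233 and 6833) and, in unstimulated cells, the secreted matrix protein gene Spp1 (8375 and 6311). Of these, Fth1 passed the size rule, and it did not do so after TPM (0.91) or quantile normalisation (0.29).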

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

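Genes whose rows were left out of the comparison, because Cufflinks gave them a status of low data or of a failed estimate in at least 1 library, were looked at for a signal after LPS. A gene was singled out where its LPS value was at least 5 FPKM, at least 2-fold higher on the log2(FPKM + 1) scale and above the upper bound of the unstimulated value. Tgtp1, an interferon-induced GTPase, stood at 0.0154 FPKM (upper bound 0.298) in the unstimulated and 19.3 in the LPS library. Clec4d, a C-type lectin receptor, stood at 61.0 (upper bound 81.2) and 164, and Rasgef1b, a Ras exchange factor, at 5.25 (upper bound 5.87) and 20.8. Rnaset2a, a secreted ribonuclease with a near-identical neighbour, stood at 94.5 (upper bound 119) and 202. For 2 transcripts without a symbol in the name table the LPS values were 6.40 (upper bound 12.3) and 5.39 (upper bound 10.7) FPKM. Their unstimulated values were 0.438 (upper bound 1.99) and 2.05 (upper bound 5.32). The rule did not use the lower bound of an LPS value, so it does not show separate intervals. These values are estimates that the authors' program marked as low data or failed in at least 1 library, and no explanation was tested for them.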

How the results depend on the processing

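Under every alternative tried, each of the 100 genes past the size rule that the naming rule takes and that could still be counted kept its direction. The larger group among called genes did not: lower genes outnumbered higher ones on the deposited FPKM, and higher genes outnumbered lower ones with a pseudocount of 5, after quantile normalisation (959 and 841) and at a fold of 4. The count of higher genes was between 577 and 1132 under the alternatives at a fold of 2, and it was 1383 at a fold of 1.5 and 359 at a fold of 4, which follows from the threshold. The count of lower genes moved further: it was 2061 with a pseudocount of 0.1, 354 with a pseudocount of 5, 2350 after rescaling to TPM, 2978 at a fold of 1.5 and 127 at a fold of 4. With separate intervals the lower genes numbered 2027, 353 and 2322 under the first 3 of these. The pseudocounts act on genes of low FPKM by construction, and the TPM rescaling moved the median change by -0.24. Median scaling moved that median by 0.07 and gave 909 higher and 1112 lower genes, of which 858 and 1112 were shared with the main setting. The size rule was lost by 17 of these 100 genes with a pseudocount of 5, by 8 after TPM, by 10 after quantile normalisation and by 1 after median scaling. Of 37 list medians, the sign changed in 7 after TPM, 7 after quantile normalisation and 4 after median scaling, all of them lists with a main median between -0.16 and 0.23. Adjacent pairs of higher genes numbered 192, and 109 with a pseudocount of 5 (fewer higher genes) and 304 with each row on its own (transcripts of 1 gene as neighbours). The median span of higher genes was 17.1 kb, and 14.6 kb with a pseudocount of 5; the cause was not tested. Of the 7929 genes called neither higher nor lower, 5303 had separate intervals, and the spread between replicates was not measured.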

Other observations

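These tests were chosen only after a result was seen: those of a larger share of fragments taken by strongly higher genes, and of G1/S against G2/M genes. The same holds for the p53, iron and receptor lists (single members such as Cdkn1a, Fth1, Tfrc and Gpr183 had been seen). It holds also for pairs without unnamed transcripts, Zfp genes after subtracting the length trend, and span in lists matched also on transcript length. The repeats of percentiles and of shuffled calls under the alternatives were chosen afterwards too (the pair counts and median spans themselves were planned). The demand that a reading hold under every alternative was also set afterwards, and it changed the reading of span, of G1/S against G2/M genes and of neighbours that fell, as the length trend changed that of Zfp genes. Genes outside the naming rule were chosen after their values were seen.

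Receptors for chemoattractants and purines changed in both directions. Of 17 counted, 5 rose and 4 fell (median 0.16, percentile 98.7; -0.08 after rescaling to TPM). The atypical chemokine receptor Ccrl2 rose from 0.836 to 131 FPKM, the fatty acid receptor Gpr84 from 0.541 to 29.4, the adenosine receptor Adora2b from 1.30 to 10.5 and the complement receptor C5ar1 from 4.74 to 14.6, and the adenosine receptor Adora2a was listed at 0 and at 3.29. The falls were those of Gpr183, the chemokine receptor Cxcr4 (20.8 to 1.40), the proton sensor Gpr65 (41.3 to 6.39) and the sphingosine phosphate receptor S1pr1 (11.9 to 2.16). Among cytokine genes named here outside the rule, Ifnb1, the gene of interferon beta, was listed at 0 in the unstimulated library and at 16.2 (13.9 to 18.4) FPKM after LPS. Il27 was listed at 0 and 146, and Csf3 at 0 and 12.8. Adora2a was not past the size rule with a pseudocount of 5.

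Targets of the DNA damage factor p53 did not move as a group. Of 17 counted, 5 rose and 3 fell (median -0.06, percentile 86.3; 0.02 after median scaling, 0.05 after quantile normalisation and 0.41 with a filter at 5 FPKM). With Cdkn1a, the genes that rose were the death receptor gene Fas (0.107 to 25.1 FPKM), Plk2 (53.2 to 305), Gdf15 (1.34 to 7.44) and Mdm2 (7.30 to 24.6), and those that fell were Sesn1 (13.9 to 0.819), Ddit4 (9.31 to 0.702) and Polk (3.89 to 0.647), with Gdf15 and Polk short of the rule with a pseudocount of 5. Among 11 iron handling genes, the importer gene Slc11a2 (7.62 to 33.2) and Fth1 rose, Hamp was listed at 0 and 1.82, and Tfrc fell (median 0.06, percentile 82.6; -0.15 after TPM and -0.60 with a filter at 5 FPKM), and Hamp was short of the rule with a pseudocount of 5. Most genes of the basic machinery stayed within the size rule. For oxidative phosphorylation 1 of 73 rose and 0 fell (median -0.06, percentile 2.61; 0.02 after median scaling), and the 1 was Ndufs5, at 2.89 FPKM after LPS and next to 0 before. Its value is uncertain, as its pseudogene Ndufs5-ps was at 70.9 and 57.2 and it did not pass the rule with a pseudocount of 5. For the constitutive proteasome 2 of 34 rose, Psmd5 (short of the rule after TPM, 0.95) and Psmd10 (uncertain, with a ratio of 2.53, 1.16 to 5.51), and 0 fell (median 0.23, percentile 95.3; -0.01 after TPM). For the lysosome the protease gene Ctsc rose and Tfeb, the regulator of lysosomal genes, fell from 5.15 to 0.943 among 25 genes (median 0.14, percentile 81.6; -0.10 after TPM and -0.08 after quantile normalisation). Ctsc was short of the rule after TPM and quantile normalisation, and Tfeb with a pseudocount of 5. For ribosome biogenesis 3 of 25 fell, Dkc1 (62.2 to 25.3), Gnl3 (94.4 to 41.9) and Rrp1b (10.0 to 4.05, short of the rule with a pseudocount of 5 and after quantile normalisation), and 0 rose (median -0.16, percentile 18.3).

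Cell cycle genes fell in the LPS library, and a larger share of fragments taken by strongly higher genes would lower all other genes alike. The list median minus that of matched random lists was -1.03. For the 28 of 30 members with a known effective transcript length, the list median itself was -1.19. It was -0.99 after subtracting the median change of genes of like effective length. Neither the shift from strongly higher genes nor a length bias thus accounts for the fall as a whole. Of G1/S and G2/M genes, 24 of 27 and 15 of 26 fell, with medians of -1.52 and -1.07, and the difference of -0.45 was at percentile 0.660 of random pairs of lists (-0.34 to 0.51). Under the alternatives this difference was between -0.47 and -0.32 and its percentile between 0.380 and 3.32, the highest with a pseudocount of 0.1, so an equal loss of both is not excluded under every setting. A hypothesis is that LPS may slow the cell cycle, with Cdkn1a higher. Cdkn1b, the gene of another cyclin-dependent kinase inhibitor, went the other way, from 7.57 to 2.82 FPKM. These 2 libraries cannot decide the hypothesis, as a difference in growth or density between the 2 cultures was not tested and stays open with 1 library each.

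Genes that rose often lay next to each other. Among 10001 neighbouring pairs of counted genes, 192 had both members higher, against 58 to 89 (central 95%) when calls were shuffled among genes of like expression. Reads shared between paralogs or overlapping genes could produce such pairs, but without pairs of one symbol stem or with overlapping loci 115 remained, against 53 to 83, and 106 against 52 to 82 when transcripts without a symbol were also left out. Runs were taken over all neighbours, with pairs of one stem included. The longest run held 9 neighbours on chromosome 1 (175451442 to 175961886), most of them of the stem Ifi. They were Ifi214, Ifi209, Ifi207, Ifi204, Mndal, Ifi211, Ifi205 and 2 transcripts without a symbol. Psmb9, Tap1, Psmb8 and Tap2 formed a run of 4 on chromosome 17. Genes that fell were neighbours in 243 pairs against 135 to 178 (215 against 121 to 163 without stems and overlaps). With a pseudocount of 5, which leaves 354 lower genes, 13 pairs remained and the central 95% of shuffled calls reached 19 (3 and 4 at a fold of 4), so a shared neighbourhood of genes that fell stays open. For genes that rose the excess without stems and overlaps was above the central 95% of shuffled calls under every alternative, least with each transcript on its own (113 against 105, inside the shuffled maximum of 115), and paralogs with unlike names and transcripts reading through into a neighbour stay open.

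Genes that rose were somewhat shorter than matched genes. Their median span was 17.1 kb, at the 1.00th percentile of matched lists (17.4 to 21.0 kb), and that of genes that fell was 24.9 kb (22.4 to 25.9 kb). The hypothesis that 3 h may leave little time to transcribe long genes and a bias by transcript length cannot be told apart here. Among genes not called, the difference in median change between the shortest and the longest of 4 equal classes of effective transcript length was 0.23, between the bounds set beforehand for a bias (over 0.5) and for its absence (0.2 or less), and effective length was known for 77.0% of the higher genes. For these 661 genes the median span was 16.8 kb, at percentile 0.380 of lists matched on expression and effective length (17.4 to 20.9 kb). That matching used coarser expression bins and 4 equal classes of length over all 8693 counted genes with an effective length. It leaves out the other higher genes and does not decide between the 2 explanations. The percentile in the lists matched on expression alone was 9.92 after median scaling, 10.8 with a filter at 5 FPKM, 26.0 at a fold of 1.5 and 4.11 with a pseudocount of 5. Under the other alternatives it was between 0 (after TPM and at a fold of 4) and 1.525 (no filter). The shorter span thus depends on the setting.

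Zinc finger protein genes with a Zfp symbol were lower as a group in the main setting: 33 of 210 fell, such as the cell cycle regulator Zfp367 (9.17 to 0.686 FPKM), and 7 rose, such as the RNA decay factor Zfp36 (34.7 to 136). The median of -0.58 was at percentile 0.280 of matched lists (-0.53 to -0.34), and at 3.34 with a pseudocount of 5. After subtracting the median of genes of like effective transcript length it was -0.22, at percentile 7.96 (lists from -0.25 to -0.04), so a group fall beyond that of other long transcripts was not shown.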
